A study of Mytilus galloprovincialis with 22 samples.

How the data were processed

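Whole-body total RNA of the Mediterranean mussel, Mytilus galloprovincialis, was hybridised to 22 one-colour Agilent arrays of a custom design, 1 array per sample. Each sample was placed in 1 of 5 developmental stages from its developmental stage label. The replicate number was taken from its title. There were 4 arrays of oocytes, 3 of veliger larvae, 5 of pediveliger larvae, 5 of settled juveniles and 5 of seed. Per the labels' protocols the replicates of a stage were biological replicates, the RNA was amplified and labelled with Cyanine-3 by Agilent's low-input protocol, and only RNA of high integrity was hybridised. Whether the replicates came from separate spawnings is not given in the sources used here.

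Each array's deposited scanner file held the intensity of 61290 spots, extracted with Agilent Feature Extraction 10.1.1.1, per the file headers. Of these, 1319 were control spots and 59971 were 60-mer probes. The processed intensity in these files had already been corrected for background and for spatial trends within the array, and low values had been replaced by a small surrogate value, per the file headers. The deposited flags for spots well above background, saturated spots and outlier spots were used as given. The series also held a table of the authors' processed intensity values, whose method is not given in the sources used here. Its columns are on a linear scale and follow the rank order of the same array's processed signal, with a Spearman correlation of 1 on every array, and its column medians lie between 38.98 and 38.99, as after quantile normalization. It was not centred by probe, and how it was scaled beyond this stays unknown. It was used as an alternative, but it is no separate check from quantile normalization.

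From the scanner files, log2 of the processed signal was taken and each array's 75th percentile over the non-control probes was subtracted. Spots flagged as outliers were left out, and saturated spots, at most 7 on an array, were kept. No probe was saturated on every array of a stage. A probe was tested if it was well above background on at least 3 arrays of at least 1 stage, which kept 46969 probes and left out 13002. The tests used limma 3.58.1 in R 4.3.3 with lmFit and eBayes. All 22 arrays entered 1 fit with a mean per stage and no covariate, which left 17 residual degrees of freedom. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 together with a difference of at least 2-fold. Consecutive stages were compared. A probe counted as highest in a stage when it passed both criteria against each of the other 4 stages, and sets of probes high in several stages were formed in the same way. A moderated F-test asked which probes differed among the 5 stages. "Rose" and "fell" are used in these senses, for the later stage relative to the earlier one, and a change of signal is always relative to the 75th percentile of the array.

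No gene names could be attached. The description of every probe in the files reads as unknown, and 0 probe identifiers were found in the table of RefSeq genes used here, so the files do not pair probes with genes. The 28 gene lists fixed before the data were examined had 0 members and were not tested. No genome was used, so no position is given for any probe. The rule fixed beforehand for this case was to give by identifier the 2 probes with the largest rise and the 2 with the largest fall in each comparison. Because values near background have no order, it was applied to called probes that were well above background on every array of both stages and whose values did not overlap between the stages. These are called the largest measured changes. Larger changes of probes near background in either stage are thereby left out. ALL2_C10158_S, for example, rose by 16.86 from oocyte to veliger and fell by 9.64 from settled juvenile to seed, but was above background on no oocyte and no seed array. The 60-mer is given for those brightest in oocytes, settled juveniles or seed that hold no conserved ribosomal RNA stretch. For the other named probes the source of the signal is open, as described among the other observations.

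The precision of the measurements is limited by the number of arrays and by how far the signal lies above background. The 75th percentile of the signal ran from 13.4 to 606.8 between arrays, and the percentage of probes well above background from 30.4% to 82.3%. On dim arrays, a probe near background sits closer to the 75th percentile than on bright arrays, so that it can appear raised there after scaling. For this reason the counts of probes that rose or fell in the consecutive comparisons, or that were highest in a stage or a run of stages, are given together with the number of probes well above background on every array of the brighter stage. For 342 sequences that were printed at more than 1 spot, the median SD between spots of an array was 0.10 on the log2 scale, against 0.43 between arrays of a stage.

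The method was tested on simulated arrays with the mean and the pooled within-stage spread of each of the 46969 real probes. In these, 200 probes were changed by known amounts. The noise was drawn independently for each probe and array, with the same spread in all stages and no array-wide brightness differences. For veliger against oocyte, 18% of probes changed by 1.5 on the log2 scale, 54% of those changed by 2, 64% of those changed by 3 and 72% of those changed by 4 were recovered, and 9 unchanged probes were called. For seed against settled juvenile these percentages were 38%, 64%, 76% and 88%, and 9 unchanged probes were called. No probe was called in the wrong direction in any of the 4 simulated comparisons. More probes were called in each real comparison than the 200 changed here, and the real arrays differed in brightness. These rates of recovery and of false calls therefore do not carry over to the real data.

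The arrays lay on 3 slides, each with several stages. Slide 1 held 3 oocyte and 0 veliger arrays, slide 2 held 0 and 1, and slide 3 held 1 and 2. Oocytes and veligers thus shared only slide 3, which held veliger replicates 2 and 3, the dimmest arrays. Slide was tested as a fixed block. Other alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, centring on the median of the tested probes, the authors' table, no filter on dim probes, a filter requiring every array of a stage, fits on only the stages compared, no fold threshold, limma's treat test against 2-fold, the replicate number as a block, and each array left out in turn. Added after the data were seen were the brightest veliger array alone, leaving out the 4 dimmest arrays, a common floor at the highest detection limit of any array (-0.78 on the log2 scale relative to the 75th percentile), removal of a trend with GC content, array brightness as a covariate, and a 75th percentile taken over the 13831 probes well above background on all arrays. Without the 4 dimmest arrays, which include veliger replicates 2 and 3, veliger replicate 4 is the only veliger array. The figures were drawn with matplotlib 3.10.9.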

Results

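Gene expression was followed through the development of the Mediterranean mussel, a bivalve whose swimming larvae settle and metamorphose into attached juveniles. The 5 stages sampled were the unfertilized oocyte (4 arrays), the veliger at 3 days post fertilization (3 arrays), the pediveliger at 20 days (5 arrays), the settled juvenile at 25 days (5 arrays) and the seed at 30 days (5 arrays). A veliger is a shelled larva that swims with a ciliated velum, a pediveliger is a late larva with a foot that is ready to settle, and seed is the farmers' name for young attached mussels. The signal differed widely between arrays. Its 75th percentile had a mean of 262.9 ± 62.9 (SD, n = 4) in oocytes, 48.0 ± 58.6 (SD, n = 3) in veligers, 91.3 ± 64.0 (SD, n = 5) in pediveligers, 326 ± 228 (SD, n = 5) in settled juveniles and 396.6 ± 139.7 (SD, n = 5) in seed. The percentage of the 59971 probes well above background was 57.1% ± 4.2 (SD, n = 4), 40.4% ± 14.3 (SD, n = 3), 54.9% ± 8.8 (SD, n = 5), 67.9% ± 9.2 (SD, n = 5) and 74.3% ± 6.6 (SD, n = 5) in the same order. Veliger replicates 2 and 3 were the dimmest arrays, with 34.1% and 30.4% of probes above background, while veliger replicate 4 had 56.8%. The median log2 signal of the spike-in controls was 10.43 ± 0.74 (SD, n = 4) on the oocyte arrays, 10.43 ± 0.75 (SD, n = 3) on the veliger arrays and 10.14 ± 0.62 (SD, n = 5) on the pediveliger arrays. It was 9.08 ± 0.20 (SD, n = 5) on the settled juvenile arrays and 9.19 ± 0.27 (SD, n = 5) on the seed arrays.

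**Figure D1:**
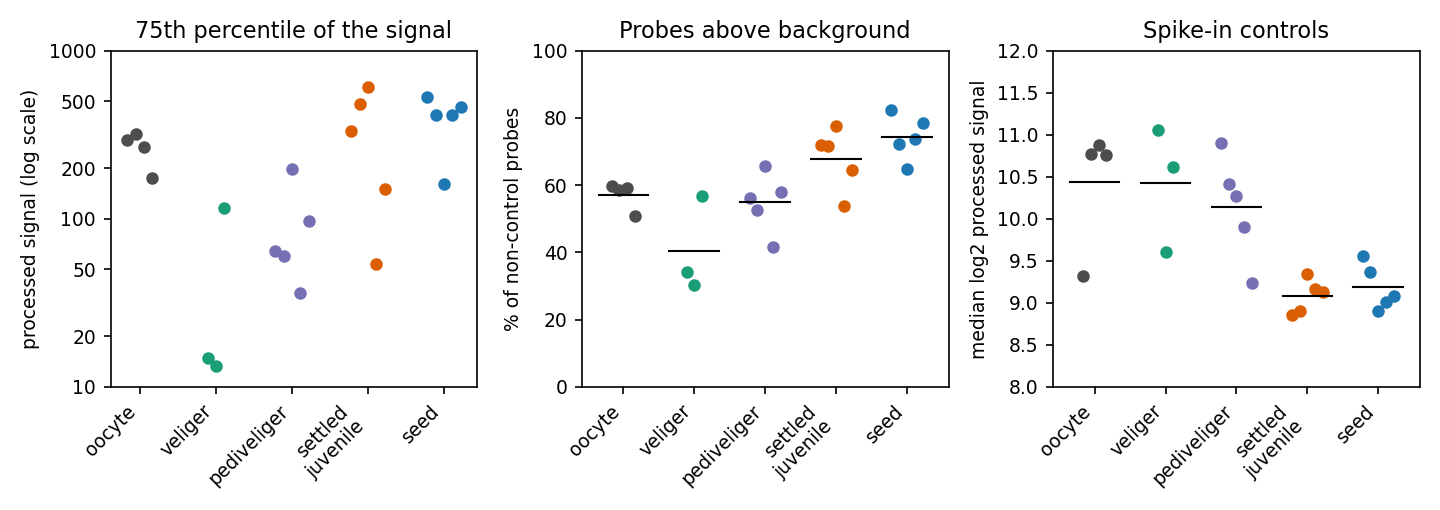
Brightness of the 22 arrays by stage, 1 point per array, with lines at the stage means in the middle and right panels. The left panel plots the 75th percentile of the processed signal on a log axis, the middle panel the percentage of probes well above background and the right panel the median log2 signal of the spike-in controls; veliger replicates 2 and 3 lie lowest on the left at 14.96 and 13.41, but not on the right.

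Oocytes stood apart from all later stages. Among the 46969 tested probes, 37567 (80%) differed among the 5 stages by the moderated F-test. The first principal component held 46.1% of the variance and separated the oocyte arrays from the rest. The second held 17.9% and ran from veliger and pediveliger arrays at one end to settled juvenile and seed arrays at the other. Stage accounted for a share of 0.97 of the variance of the second component and the log2 75th percentile of the array for 0.708, so that stage and brightness overlap along it. Between oocytes and any later stage, 27167 to 28706 probes were called, and the Pearson correlation of the stage means, taken across probes that are not independent replicates, was 0.684 to 0.712. The same correlation was 0.902 between veliger and pediveliger, 0.906 between pediveliger and settled juvenile and 0.962 between settled juvenile and seed. Single arrays of the same stage correlated with a mean of 0.953 in oocytes, 0.892 in veligers, 0.909 in pediveligers, 0.922 in settled juveniles and 0.931 in seed. Averaging over arrays raises a correlation, so these values cannot be set beside those of the stage means. With a common floor for all arrays, chosen after the data were seen, 20926 probes differed among the stages.

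**Figure D2:**
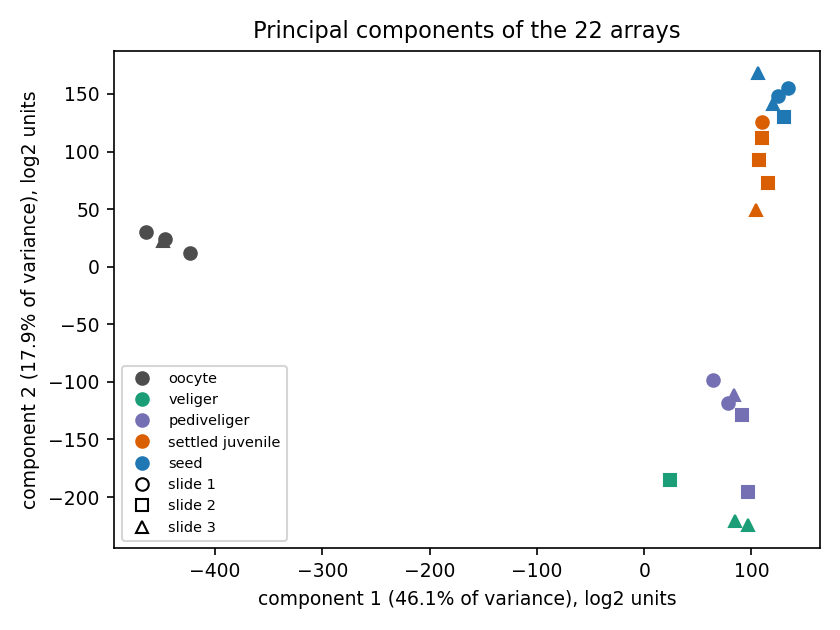
Principal components of the tested probes, 1 point per array, coloured by stage and shaped by slide. The horizontal axis is component 1 (46.1% of the variance) and the vertical axis component 2 (17.9%), both in log2 units. The 4 oocyte arrays lie far to the left of all others. Slide 1 holds 3 of them, slide 2 holds 0 and slide 3 holds 1.

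The comparison of veligers with oocytes spans fertilization and the first 3 days of development. It gave the most changes of the 4 consecutive comparisons, with 18981 probes higher and 9725 lower in veligers, 61.1% of those tested. The falls had a median log2 change of -2.00, and 1780 probes fell at least 8-fold. Nearly all of them were measured in oocytes, since 9697 of the 9725 were well above background on all 4 oocyte arrays. The rises had a median log2 change of 2.92, but only 6448 of the 18981 were well above background on all 3 veliger arrays. Another 6145 were above background on no veliger array, and 5246 of these were above background on no array of either stage, so that no level was measured for them. Probes that were above background on every veliger array and on no oocyte array numbered 1009, and all 1009 rose. The reverse held for 2809 probes, of which 1238 fell. The scaling favours this contrast, so it is no result about the stages. Relative to the scaling of each array, the detection limit was higher on the dim veliger arrays than on the oocyte arrays. That favours calling the 1009 probes as rises and hinders calling the 2809 as falls.

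The 2 largest measured falls were those of ALL2_C90136_P and ALL2_C11669_P. The first dropped by 7.60 ± 0.44 (SE) on the log2 scale (adjusted p = 1.36e-11), from 7.41 ± 0.33 (SD, n = 4) in oocytes to -0.19 ± 0.09 (SD, n = 3) in veligers, and its 60-mer is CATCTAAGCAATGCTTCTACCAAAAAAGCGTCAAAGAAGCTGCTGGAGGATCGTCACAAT. The second dropped by 7.51 ± 0.41 (SE) (adjusted p = 5.29e-12), from 7.69 ± 0.28 (SD, n = 4) to 0.18 ± 0.11 (SD, n = 3), and its 60-mer is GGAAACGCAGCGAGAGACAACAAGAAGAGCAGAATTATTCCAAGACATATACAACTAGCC. Both stayed at least 2-fold below the oocyte level at all later stages. The largest measured rises were 14.9 ± 1.16 (SE) for ALL2_REP_C16996_P (adjusted p = 1.17e-09) and 12.3 ± 0.83 (SE) for ALL2_REP_C40767_P (adjusted p = 1.41e-10). Their size depended on the scaling, from 11.54 (authors' table) to 15.24 (scaled on probes above background on all arrays) for the first and from 9.64 to 12.64 with the same 2 scalings for the second. These 2 probes also stood at 10.73 ± 0.61 (SD, n = 5) and 10.69 ± 0.76 (SD, n = 5) in pediveligers and at -1.12 ± 2.83 (SD, n = 5) and 4.41 ± 1.80 (SD, n = 5) in seed.

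The direction of the changes between oocyte and veliger depended on the processing. Rises were 66.1% of the calls, against 41.2% with quantile normalization, 41.1% with the authors' table, 54.6% when centred on the median of the tested probes, 73.8% when scaled on probes above background on all arrays and 75% with normexp. The median log2 change over all tested probes was 0.74, against -0.24, -0.28, 0.26, 1.08 and 1.03 with these in the same order. Quantile normalization and the authors' table gave close results, with 23072 and 22956 probes called, and are no separate checks. Rises were 50.3% of the calls, and the median log2 change 0.05, with a trend with GC content removed, which also re-centres each array. They were 76% with no filter on dim probes and 57.2% with array brightness as a covariate. With veliger replicate 4 as the only veliger array, the median log2 change over all tested probes was 0.4. It was also 0.4 without the 4 dimmest arrays, which leaves the same lone veliger array and is no separate check. With a common floor, 4908 probes rose and 6670 fell. With slide as a block 26444 probes were called, and 89.2% of the probes called without it were among them in the same direction.

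The comparison of pediveligers with veligers covers larval growth between 3 and 20 days. In pediveligers 4119 probes were higher and 4931 lower, 19.3% of those tested, with median log2 changes of 1.65 and -1.63. Of the rises, 3539 were well above background on all 5 pediveliger arrays, and of the falls, 3266 on all 3 veliger arrays. In all, 499 probes were above background on every pediveliger array and on no veliger array, and 370 of them rose. ALL2_REP_C16338_S rose by 4.99 ± 0.38 (SE) (adjusted p = 3.83e-08), from 0.10 ± 0.31 (SD, n = 3) to 5.10 ± 0.40 (SD, n = 5), and it was higher in pediveligers than in every other stage. ALL2_C52301_P rose by 5.89 ± 1.38 (SE) (adjusted p = 0.00465), with wide spread between the pediveliger arrays, at 5.92 ± 2.21 (SD, n = 5). Without the 4 dimmest arrays, which leaves veliger replicate 4 as the only veliger array, the change was 6.83. The probe was then no longer called, though its change was not smaller. ALL2_REP_C18872_AS fell by 8.98 ± 0.89 (SE) (adjusted p = 1.09e-06), from 8.37 ± 1.92 (SD, n = 3) to -0.62 ± 1.42 (SD, n = 5). ALL2_C50320_P fell by 8.88 ± 1.19 (SE) (adjusted p = 3.65e-05), from 10.37 ± 1.5 (SD, n = 3) to 1.5 ± 2.11 (SD, n = 5), and it was above background on no oocyte array. With 5 other scalings the change was -9.09 to -6.94 for ALL2_REP_C18872_AS and -8.99 to -6.7 for ALL2_C50320_P.

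The number of probes that differed between veliger and pediveliger rested in part on single veliger arrays, at 6025 without veliger replicate 2, 13821 without veliger replicate 4 and 3804 with replicate 4 as the only veliger array. In the last of these the spread is taken from the other stages, so the lone array is assumed to vary as they do. It was 4287 when only these stages were fitted, 4819 with a common floor and 1621 with normexp. Rises were 45.5% of the calls, against 58.2% with quantile normalization, 59.2% with the authors' table, 61.5% when scaled on probes above background on all arrays, 75.9% with normexp, 37% when centred on the median of the tested probes and 35.5% without veliger replicate 4. The median log2 change over all tested probes was -0.26, against 0.05, 0.07, -0.06, -0.30, -0.37 and -0.42 with these in the same order, and the percentage of rises did not follow it throughout. Rises were 61.2% with the GC trend removed and 63.4% with limma's treat test against 2-fold. With veliger replicate 4 as the only veliger array, the median log2 change over all tested probes was 0.12. It was 0.07 without the 4 dimmest arrays, which leaves the same lone veliger array and is no separate check. With slide as a block 7434 probes were called, and 78.1% of the probes called without it were among them in the same direction.

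The comparison of settled juveniles with pediveligers brackets settlement and metamorphosis. In settled juveniles 3346 probes were higher and 3259 lower, 14.1% of those tested, with median log2 changes of 1.83 and -1.88. Rises of at least 8-fold were seen for 800 probes and falls of that size for 734. Of the rises, 3049 were well above background on all 5 settled juvenile arrays, and of the falls, 1946 on all 5 pediveliger arrays. ALL2_C2076_S rose by 5.56 ± 0.92 (SE) (adjusted p = 0.000357), from 1.91 ± 2.32 (SD, n = 5) to 7.47 ± 0.23 (SD, n = 5), and its 60-mer is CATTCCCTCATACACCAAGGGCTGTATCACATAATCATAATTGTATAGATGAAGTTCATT. ALL2_REP_C25610_S rose by 5.24 ± 0.36 (SE) (adjusted p = 2.63e-08), from -0.43 ± 0.52 (SD, n = 5) to 4.81 ± 0.43 (SD, n = 5). Its 60-mer is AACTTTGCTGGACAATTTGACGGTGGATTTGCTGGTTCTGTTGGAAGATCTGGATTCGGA. Both were high in seed too, at 6.75 ± 0.74 (SD, n = 5) and 5.26 ± 0.62 (SD, n = 5), and neither was above background on any oocyte array. ALL2_C10158_S fell by 7.68 ± 0.63 (SE) (adjusted p = 1.45e-07), from 10.72 ± 0.63 (SD, n = 5) to 3.04 ± 1.44 (SD, n = 5), and it was above background on no oocyte and no seed array. ALL2_REP_C43016_N fell by 7.18 ± 0.75 (SE) (adjusted p = 2.25e-06), from 6.51 ± 1.0 (SD, n = 5) to -0.67 ± 1.24 (SD, n = 5).

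Between pediveliger and settled juvenile, 2560 probes were called with a common floor and 9925 with array brightness as a covariate, and rises were 50.7% of the calls against 24.9% with normexp and 62% with a common floor. The median log2 change over all tested probes was -0.05, and -0.42 with normexp. With slide as a block 6673 probes were called, and 92.2% of the probes called without it were among them in the same direction.

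Seed and settled juveniles, sampled 5 days apart, differed least. In seed 433 probes were higher and 323 lower, 1.6% of those tested, with median log2 changes of 2.72 and -3.99. Of the rises, 406 were well above background on all 5 seed arrays, and of the falls, 142 on all 5 settled juvenile arrays. ALL2_REP_C88043_P rose by 7.25 ± 0.55 (SE) (adjusted p = 4.64e-07), from -1.87 ± 0.38 (SD, n = 5) to 5.39 ± 0.60 (SD, n = 5). Its 60-mer is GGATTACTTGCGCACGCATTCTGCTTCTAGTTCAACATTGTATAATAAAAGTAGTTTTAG. ALL2_REP_C54381_P rose by 7.08 ± 0.76 (SE) (adjusted p = 3.66e-05), from -2.95 ± 0.41 (SD, n = 5) to 4.12 ± 0.26 (SD, n = 5), and by 5.55 with normexp and 4.9 with a common floor. Its 60-mer is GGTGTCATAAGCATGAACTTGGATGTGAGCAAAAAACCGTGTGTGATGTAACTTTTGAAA. Both were higher in seed than in every other stage, and neither was above background on any veliger or pediveliger array. ALL2_C310_S fell by 4.86 ± 0.96 (SE) (adjusted p = 0.00913), from 5.42 ± 0.47 (SD, n = 5) to 0.56 ± 1.65 (SD, n = 5). ALL2_REP_C24001_S fell by 4.79 ± 0.77 (SE) (adjusted p = 0.00197), from 8.14 ± 0.68 (SD, n = 5) to 3.35 ± 1.52 (SD, n = 5). The count of 756 fell to 419, 465 and 435 without settled juvenile replicates 2, 3 and 5 and to 470 without seed replicate 5, and it was 1197 when only these stages were fitted and 1301 without the 4 dimmest arrays. Rises were 57.3% of the calls, against 73.5% (880 higher and 317 lower) when only these stages were fitted, 71.3% with array brightness as a covariate and 67.9% with the filter requiring every array of a stage, and 438 probes were higher and 104 lower with a common floor. With slide as a block 557 probes were called, and 70.6% of the probes called without it were among them in the same direction.

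**Figure D3:**
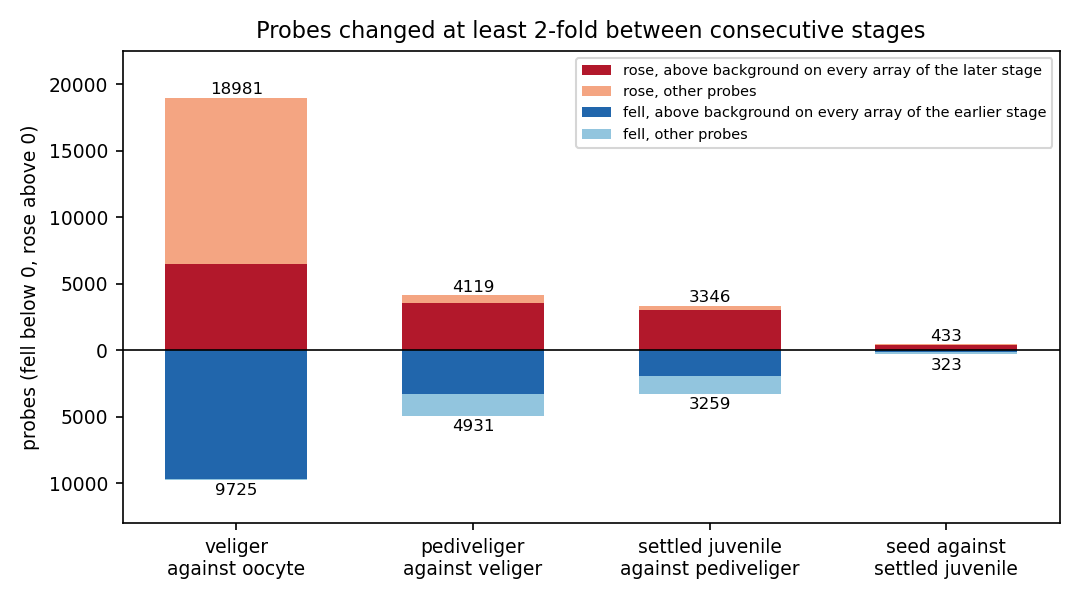
Probes that rose (above 0) or fell (below 0) at least 2-fold at an adjusted p under 0.05 in each consecutive comparison, in numbers of probes, with the totals at the bar ends. Dark parts are probes well above background on every array of the brighter stage; of the 18981 rises from oocyte to veliger these are 6448.

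**Figure D4:**
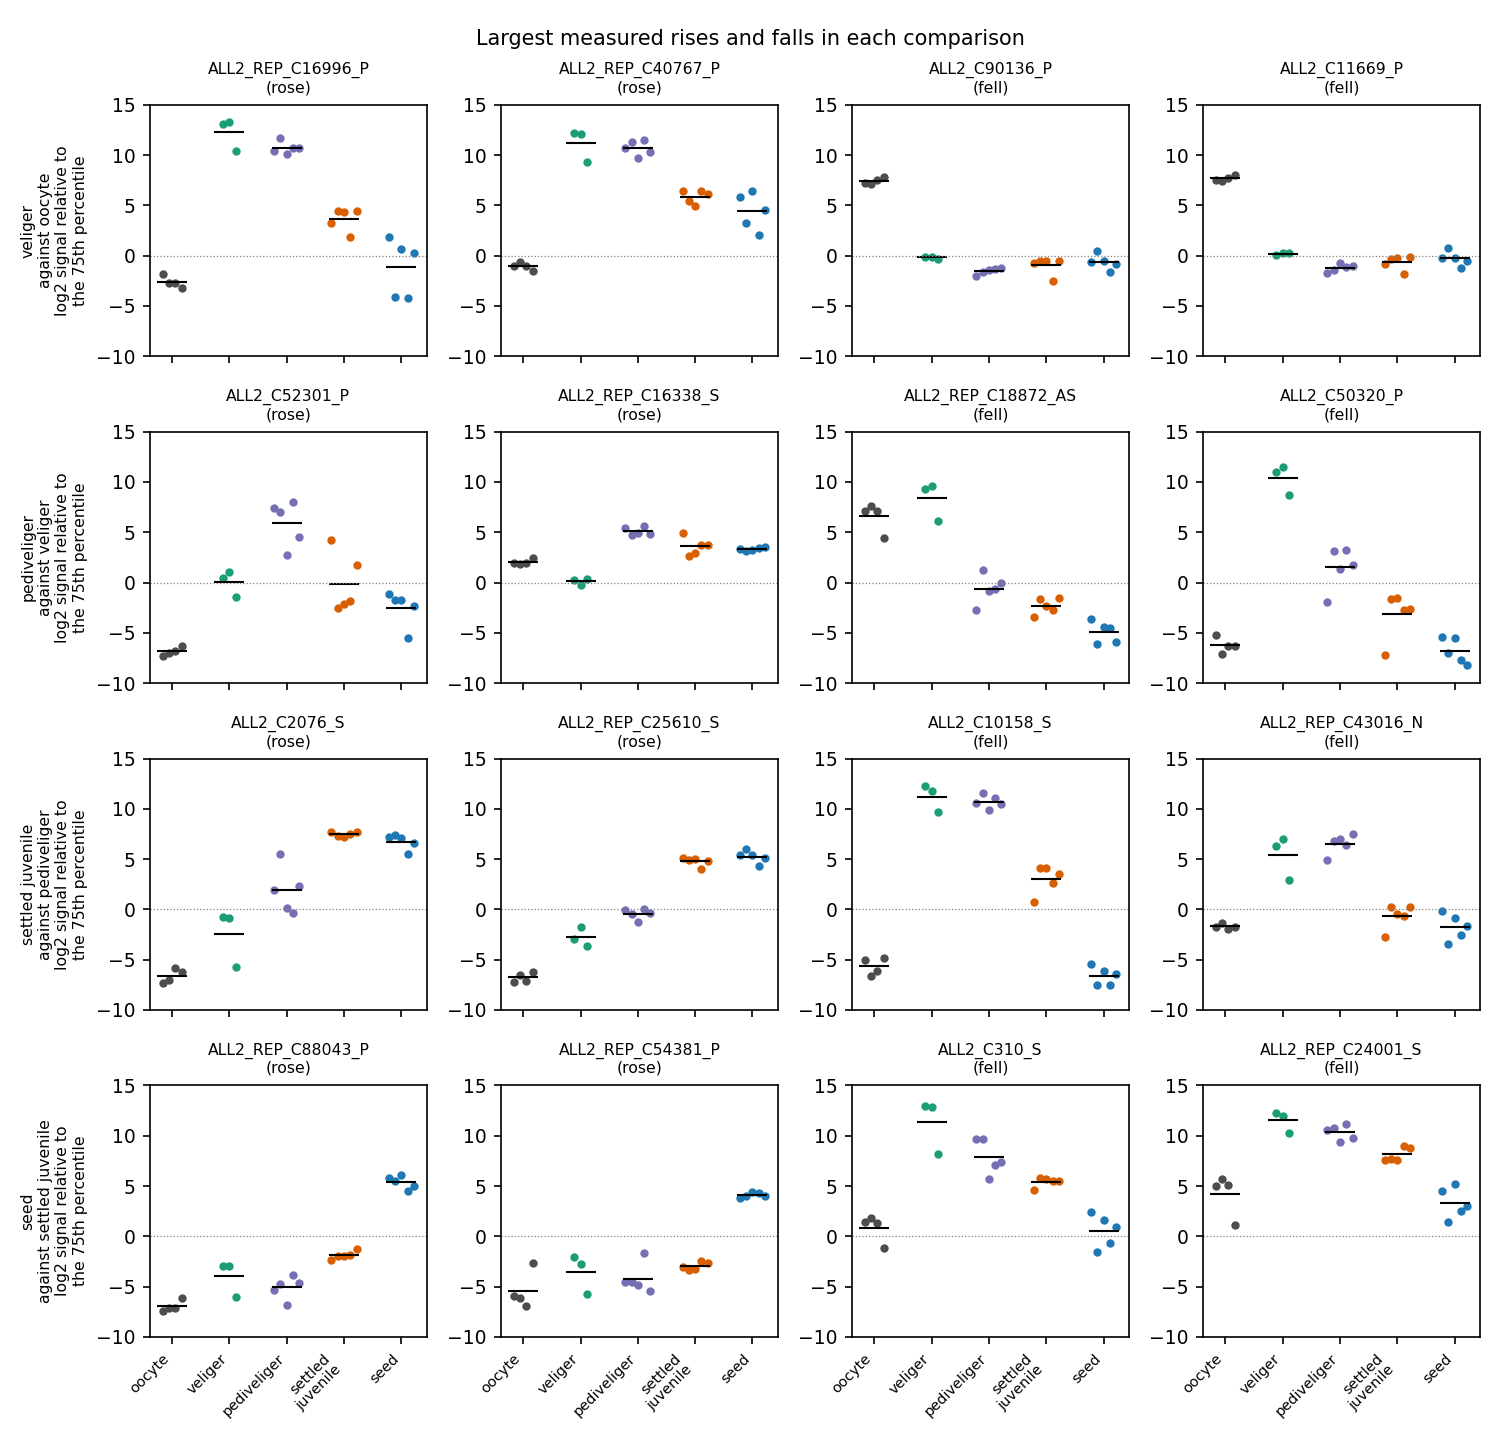
Log2 signal relative to the array's 75th percentile for the 2 largest measured rises and the 2 largest measured falls of each comparison (rows), 1 point per array, with lines at the stage means and a dotted line at 0. Only probes above background on every array of both stages compared were eligible, so larger changes of other probes are left out. ALL2_C90136_P is at 7.41 in oocytes and near 0 in veligers, and ALL2_REP_C54381_P is at 4.12 in seed and at -2.95 in settled juveniles.

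Probes that marked a single stage were most numerous in oocytes. In all, 6717 probes were at least 2-fold higher in oocytes than in each of the other 4 stages, by a median log2 margin of 1.79 over the next stage, and 6708 of them were well above background on all 4 oocyte arrays. In veligers 1483 probes were highest, of which 1077 were above background on all 3 veliger arrays, with a median margin of 1.72. In pediveligers 341 probes were highest, 300 of them above background on all 5 arrays, with a median margin of 1.66. In seed 197 probes were highest, all 197 above background on the 5 seed arrays, with a median margin of 2.41. Only 22 probes were highest in settled juveniles, 11 of them above background on all 5 settled juvenile arrays, and other groupings of the settled juvenile and seed arrays gave as many too often to exclude chance. With normexp 188 probes were highest in veligers, 108 in pediveligers and 313 in seed, and limma's treat test against 2-fold gave 3426, 199, 48, 1 and 41 in order of age. The oocyte count was 4372 when scaled on probes above background on all arrays. The veliger count was 906 with the GC trend removed, 930 with array brightness as a covariate, 886 without veliger replicate 2, 859 without replicate 3 and 3357 without replicate 4. The seed count was 125 without settled juvenile replicate 2, 128 without seed replicate 5, 334 with a common floor and 487 with array brightness as a covariate. The settled juvenile count ran from 5 without settled juvenile replicate 3 to 1.0e+02, rounded, without settled juvenile replicate 1, and was 6 and 7 without settled juvenile replicates 2 and 5 and 7, 14 and 9 without veliger replicates 2, 3 and 4.

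Other sets of probes marked runs of consecutive stages. Lower in oocytes than in all 4 later stages were 11343 probes, although only 3301 of them were above background on every array of the later stages. Pediveligers, settled juveniles and seed were higher than both earlier stages for 1334 probes, of which 1158 were above background on every array of these 3 stages. Settled juveniles and seed were higher than all earlier stages for 1160 probes, 1136 of them above background on every array of both. The mean log2 signal of this set was -3.72 in oocytes, -2.61 in veligers and -2.04 in pediveligers, and 1.18 in settled juveniles and 1.82 in seed. Veligers and pediveligers were higher than the other 3 stages for 1014 probes, with 588 above background on every array of both. The mean log2 signal of these was 1.08 and 0.27 in the larval stages, against -4.00 in oocytes and -3.28 in seed. Oocytes and veligers were higher than all later stages for 517 probes, 377 of them above background on every array of both. Veligers, pediveligers and settled juveniles were higher than oocytes and seed for 108 probes, with 45 above background on every array of the 3 stages, and pediveligers and settled juveniles were higher than the other 3 stages for 13, with 11 above background on every array of both. With a common floor these sets held 1977, 701, 779, 321, 296, 30 and 11 probes in the same order.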

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

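Of the tests in this part, the 2 on the signal of the brightest probes and the splits for the probes highest in a stage were chosen after the results had been seen, replacing a share of summed signal that falls with brightness by construction and groupings of all 22 arrays that mix oocytes into each group, as were the alternatives with veliger replicate 4 alone and with the GC trend removed. Values of single arrays were screened in 40 groups of 4 or 5 arrays, where chance alone picks out about 1 group in 20, and 5 values on 4 arrays stood apart. Oocyte replicate 4 had 50.92% of probes well above background, against 58.57% to 59.89% on the other oocyte arrays. Oocyte replicate 1 had a median log2 spike-in signal of 9.32, against 10.76 to 10.88. Seed replicate 3 had a log2 75th percentile of 7.34, against 8.69 to 9.06, and its 100 brightest probes held 36.8% of its summed signal, against 23% to 24.2%. ALL2_REP_C25610_S stood at 4.06 on settled juvenile replicate 4, against 4.86 to 5.13 on the other settled juvenile arrays.

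The veliger and pediveliger arrays were dim, with wide differences within a stage. The spike-in controls argue against hybridisation, washing or scanning as the whole source. Their median log2 signal had a mean of 10.43 both on the dim veliger arrays and on the brighter oocyte arrays. Within veligers it was 11.058 and 9.605 on the dim replicates 2 and 3 and 10.622 on replicate 4. Its slope on the log2 75th percentile over the 22 arrays was -0.183 ± 0.099 (SE). This slope also carries a difference between stages, since the mean was 10.14 in pediveligers but 9.08 in settled juveniles and 9.19 in seed. Stage alone is also ruled out, because the SD of the log2 75th percentile among the veliger arrays was 1.75, and slide explained a share of 0.25 of the variance of this percentile, which leaves slide open. A few very bright probes taking signal from the rest is argued against as the whole source of the dim veliger and pediveliger arrays. The summed signal of each array's 100 brightest probes tended to be lower, not higher, on dim arrays. Settled juvenile replicate 4 was an exception. Its 75th percentile was 54.1 and this summed signal 33.3 in units of 1e+06, against 25.2 to 35 on the other, brighter settled juvenile arrays. Over the 22 arrays, the Spearman rho of the summed signal of these 100 probes with the log2 75th percentile was 0.796 and the Pearson r 0.866. Both had p = 1e-05 by permutation with 100000 resamples, the smallest these can give. The arrays were permuted across stages, so the p-values also carry the difference between stages. They do not measure a relation within a stage. Without the 2 arrays farthest from the median percentile, r was 0.773. In units of 1e+06 the summed signal was 17.8 and 15.6 on veliger replicates 2 and 3 against 28.7 on replicate 4. A part in the dimness stays open for these probes. They held 59.4% and 58.7% of the summed signal on veliger replicates 2 and 3 and 38.7% on replicate 4, where the 75th percentile was 14.96, 13.41 and 115.6, so their signal fell less than that of the rest. The within-stage slope of their log2 summed signal on the log2 75th percentile was 0.275 ± 0.032 (SE) over the 8 veliger and pediveliger arrays, but at 0.049 ± 0.047 (SE) it was low over the 14 other arrays too, as a general compression of bright spots would also give. The amount of RNA labelled and a difference between the larvae were not tested and stay open.

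The counts of changed probes from oocyte to veliger and from veliger to pediveliger may owe part of their size to the 2 dim veliger arrays. With veliger replicate 4 as the only veliger array, 83.4% of the probes called against oocytes and 67% of those called between veliger and pediveliger kept a change of at least 2-fold in the same direction, which neither clears nor establishes the dim arrays as the source. GC content of the probes is argued against as the whole cause, since at least 82.3% of the called probes were still called in both comparisons with the GC trend removed. Removing the trend also re-centres each array, so the balance of rises and falls after it does not bear on GC content. A biological difference between the stages stays open as well, for the calls that rest on probes above background.

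The real grouping gave the most probes for all of the 10 counts except those for probes highest in veligers and in settled juveniles. Splits that mix stages also widen the spread within each group, which lowers their counts. The median count of the other splits of 2 stages was 0. The real grouping is thus favoured, and its rank is not corrected for the number of counts. These ranks argue against an arbitrary grouping of the arrays as the source, but do not exclude chance. From oocyte to veliger the real count of 28706 was the highest of 35 splits, and the next was 21530, in a split that parted 3 oocyte arrays from the rest. From veliger to pediveliger the real count of 9050 was the highest of 56 splits. The next, 8437, set veliger replicates 2 and 3 with pediveliger replicate 4, the 3 dimmest of these arrays, against the rest. That split keeps 2 of the 3 veliger arrays together, so brightness and stage cannot be told apart in it. From pediveliger to settled juvenile the real count of 6605 was the highest of 100 splits, with 1357 next, and from settled juvenile to seed the real count of 756 was the highest of 100, with 448 next. Among 100 groupings of all 22 arrays, the real one had the most probes differing among the stages, with 37567 against 22571 in the next.

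For the probes highest in a stage, its arrays and those of a neighbouring stage were split anew while all other arrays stayed in place. The real count was the highest for oocytes, with 6717 against 169 in the next of 35 splits with veligers, for pediveligers, with 341 against 18 in the next of 100 splits with settled juveniles, and for seed, with 197 against 39 in the next of 100 splits with settled juveniles. For veligers, 2 of the 56 splits with pediveligers gave at least as many as the real 1483, the real one included. The other gave 2514 and put veliger replicates 2 and 3 with pediveliger replicate 4, the 3 dimmest of these arrays, so the veliger count cannot be separated from brightness by this test. For settled juveniles, 6 of the 100 splits with seed gave at least the real 22, the real one included, with 197 as the highest other, so chance cannot be excluded. That highest one gave the settled juvenile place to all 5 seed arrays, and without it 5 of 99 splits gave as many, with 37 as the highest other.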

How the results depend on the processing

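The 16 changes of named probes kept their direction in every recomputation made of them. They stayed past the threshold in 591 recomputed values and missed it in 1. They were not recomputed with no fold threshold or with limma's treat test against 2-fold. They were picked as large in these data and many fits only drop an array of another stage, so these are no independent checks. The 1 exception was ALL2_C52301_P between veliger and pediveliger without the 4 dimmest arrays (6.83 against 5.89, with a wider SE). With 5 other scalings the size of 7 of the 16 moved over 2-fold, the most for ALL2_REP_C16996_P (11.54 to 15.24, against 14.9) and ALL2_REP_C40767_P (9.64 to 12.64, against 12.3), followed by ALL2_C50320_P (-8.99 to -6.70, against -8.88), ALL2_REP_C18872_AS (-9.09 to -6.94, against -8.98), ALL2_REP_C54381_P (5.55 to 7.24, against 7.08), ALL2_C10158_S (-7.72 to -6.32, against -7.68) and ALL2_REP_C43016_N (-7.33 to -6.14, against -7.18). The counts depended more on the processing. Within 1.5 times the main count were 37, 31, 36 and 31 of 39 values in the 4 comparisons in order of age. For the values outside this range the cause was not tested, except that fewer probes can pass a stricter test or filter and fewer arrays give less power. Many of the 39 fits only drop 1 array, the authors' table is no separate check from quantile normalization, and totals can hide changed calls. Quantile normalization kept 18326 of 28706 calls for veliger against oocyte, and normexp 3847 of 6605 for settled juvenile against pediveliger. Limma's treat test against 2-fold called 18109, 1141, 1335 and 164 probes in the 4 comparisons and 3426, 199, 48, 1 and 41 as highest in the 5 stages, both in order of age. Normexp gave 1621 for pediveliger against veliger and 188, 108 and 313 for highest in veliger, pediveliger and seed. Quantile normalization gave 55 and 305 for highest in settled juvenile and seed, and the authors' table gave 50 for settled juvenile. The filter requiring every array of a stage gave 11 for settled juvenile. Fits on only the stages compared gave 4287 for pediveliger against veliger and 1197 for seed against settled juvenile. Slide as a block gave 13 for highest in settled juvenile and moved no other count by over 1.5 times.

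Of the alternatives chosen after seeing the data, veliger replicate 4 alone gave 3804 for pediveliger against veliger and 508, 10 and 329 for highest in veliger, settled juvenile and seed, with the spread taken from the other stages, so that the lone array is assumed to vary as they do. Leaving out the 4 dimmest arrays gave 5481 for pediveliger against veliger, 1301 for seed against settled juvenile, and 698 and 407 for highest in veliger and seed. The common floor gave 11578, 4819 and 2560 for the first 3 comparisons, 34 and 334 for highest in settled juvenile and seed, and 20926 differing among the stages. It takes away differences among values below the highest detection limit, and 39.8%, 51%, 36.9% and 34% of the called probes in the 4 comparisons were still called. Removing the GC trend gave 906 for highest in veliger. Brightness as a covariate gave 9925 for settled juvenile against pediveliger, 1307 for seed against settled juvenile, and 930, 13 and 487 for highest in veliger, settled juvenile and seed. Scaling on the probes above background on all arrays gave 4372 for highest in oocyte.

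Leaving out each array in turn gave 26039 to 29269 probes for veliger against oocyte, 6025 to 13821 for pediveliger against veliger, 5206 to 7526 for settled juvenile against pediveliger and 419 to 1106 for seed against settled juvenile. It gave 6325 to 6743 highest in oocyte, 859 to 3357 in veliger, 258 to 357 in pediveliger, 5 to 1.0e+02 (rounded) in settled juvenile and 125 to 247 in seed, and 35325 to 39054 differing among the stages. With the replicate block, 28308, 7517, 6193 and 622 probes were called in the 4 comparisons, and 27786, 7312, 5955 and 592 of these were called without the block in the same direction. Whether the numbers pair the samples was not settled. Same-numbered arrays of consecutive stages had mean correlations of -0.033, -0.088, 0.091 and 0.075 between their deviations from the stage means. For arrays with different numbers these were 0.006, 0.017, -0.022 and -0.017. Of the 22 arrays, 7 correlated best with an array of their own number, and how many chance would give was not tested. The planned tests of gene lists were not run, because no probe had a name. What could be measured was limited by signal over background, with 5651 probes above background on no array and 13831 on all 22.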

Other observations

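Both tests on the larval probes described next were chosen after their values had been seen. Among 1271 probes that were lower in seed than in veliger and in pediveliger and above background on every array of both larval stages, the 100 with the largest fall dropped by at least 7 on the log2 scale. They held 3.4% ± 1.6 (SD, n = 3) of the summed signal in veligers and 1.5% ± 0.5 (SD, n = 5) in pediveligers, against 0.2% ± 0.1 (SD, n = 4) in oocytes and 0.2% ± 0.1 (SD, n = 5) in settled juveniles. Within the veliger stage the median slope of their unscaled log2 signal on the log2 75th percentile was 0.075 (interquartile range -0.142 to 0.614, n = 3 arrays), against 1.008 (0.822 to 1.171) for 902 equally bright probes, a ratio of 0.074. Within the pediveliger stage it was 0.694 (0.252 to 1.186, n = 5 arrays), against 1.117 (0.896 to 1.308), a ratio of 0.621. RNA that is not part of the mussel's messenger RNA could give slopes well under those of equally bright probes, but only the 3 veliger arrays show this, 2 of them dim, which leaves this explanation open. Ribosomal RNA was tested with 8 conserved stretches, which only 8 of the 46969 tested probes held. The median log2 signal of these 8, relative to the 75th percentile, was 3.36 in oocytes, 8.59 in veligers and 6.2 in pediveligers. It was 5.41 in settled juveniles and 1.95 in seed, so it was highest in the 2 larval stages. Of the 100 probes, 2 held such a stretch, 117 times the share among all tested probes. So few matches leave ribosomal RNA open for the rest of the set. The criterion that at least 10 of the 100 hold one was added after these 2 had been seen, and without it, by the share alone, ribosomal RNA would have counted as met. Larval genes of the mussel whose levels vary between cultures were not tested and stay open too.

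Probes came with identifiers ending in P, N, S or AS, whose meaning is not given in the sources used here. Identifiers ending in AS made up 9.7% of the tested probes. They were 3.8% of the 6717 highest in oocytes, 9% of the 1483 highest in veligers and 7.6% of the 341 highest in pediveligers. Among the 22 highest in settled juveniles they were 0%, and among the 197 highest in seed 4.1%. These differences were not tested. In 290 pairs that share all but the ending S or AS and were above background on all arrays, 8.4% of the 3440 pairs tested, the changes of the 2 probes had a Pearson r across pairs of 0.132, 0.297, 0.124 and 0.201 in the 4 comparisons in order of age. Random re-pairing gave -0.004, -0.002, 0.003 and -0.003. From oocyte to veliger both probes were called in 124 pairs, in the same direction in 108.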
